A study of Mus musculus with 8 samples.

How the data were processed

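The series holds 8 libraries from wild-type mice bearing MC38-EGFP tumours, 2 for each of 4 groups: EGFP-negative cDC1, EGFP-positive cDC1, EGFP-negative cDC2 and EGFP-positive cDC2, grouped by their titles. Per the labels' protocols the cells were isolated by fluorescence-activated sorting, full-length cDNA was made by a published low-input method and libraries were prepared with a KAPA kit. Trimmomatic 0.39, STAR 2.7.5c and Cufflinks 2.2.1 are named in the submitters' processing notes, together with the mm10 build. The read counter, the gene annotation and the use of strand are not given in the sources used here. The deposited table holds raw read counts, whole numbers for 24369 gene symbols in 8 columns. Each column was matched to its sample by name, and 0 columns were left without a sample. Of the symbols, 23204 (95.2%) were found in GENCODE M21 and 23075 (94.7%) in RefSeq for GRCm38. No genome sequence was used.

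Library totals were 21323090, 22195681, 20039994, 17869441, 20070316, 20357915, 19277974 and 18201995 counts for EGFP-negative cDC1 replicates 1 and 2, EGFP-positive cDC1 replicates 1 and 2, EGFP-negative cDC2 replicates 1 and 2 and EGFP-positive cDC2 replicates 1 and 2. A floor of 3 counts in 1 library corresponds to 0.135 to 0.168 CPM before TMM scaling. Where all libraries of a group had 0 counts, a fold was computed against 3 counts over the group and is a lower bound. PCR reads without molecular identifiers are not independent molecules, so such floors cover counting error only. The common dispersion was 1.28, a biological coefficient of variation of 1.13, so differences of modest size were seldom detectable with 2 libraries a group.

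Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group left 11394 genes, libraries were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest were followed by Benjamini-Hochberg adjustment over all genes tested, with an adjusted p under 0.05 as the threshold. All 8 libraries entered one model with 1 mean per group, from which 5 contrasts were taken: EGFP within each subset, subset within each EGFP fraction, and the interaction. A model with subset and EGFP as additive terms gave the remaining 2, each over 4 libraries a side. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Gene lists were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset inter-gene correlation of 0.01 and again with an estimated one, and adjusted over the lists within each contrast. List medians are of the voom log2 fold changes unless a bound is mentioned, where the median is of log2 ratios of mean CPM with members at 0 counts in a group set to their bound. Of 28 lists fixed before the data were examined, 26 had at least 3 tested members; those for T and NK cells and for red blood cells had 0. Members were also counted with p-values adjusted over the list alone.

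Genes were named by a rule fixed before the data were examined. In each contrast these were the 10 genes of largest positive and the 10 of largest negative log2 fold change among those past the threshold with a mean of at least 10 CPM, no overlap between the groups and no predicted-gene or clone symbol. Where fewer than 5 passed in a direction, the genes of smallest p up to 5 were given as values. Dpp4 and 12 marker genes of dendritic cells were always read, and in each list described up to 4 members of smallest p with a mean of at least 5 CPM. Not every gene that the rule gives is described. Other genes of the fixed lists whose levels are given per library, such as Lyz2, Arg1, Apoe and Sparc, were chosen after their values were seen.

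Alternatives fixed in advance were DESeq2 1.42.0, RLE scaling, no low-count filter, a filter of at least 10 CPM in at least 2 libraries, no robust estimation, voom with library quality weights, a fit of the compared libraries alone, the 4-group model for the averaged contrasts, the replicate number as a block, an estimated inter-gene correlation and leaving out each library in turn. Removal of Rn45s was added after its share of the counts was seen. Where leaving out a library left a group with 1 library, the model took its spread from the other groups. Random gene lists, 10000 for each list and matched on mean expression, served to place list medians, and single libraries were compared as log2 of CPM plus 1.

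The steps were tested on simulated data made from the real means, dispersions and library sizes. Each gene was given the same dispersion in all groups. The real EGFP-positive cDC1 replicates agreed less (Pearson correlation 0.559) than those of the other groups (0.781 to 0.832). The simulated recovery may therefore not hold for EGFP in cDC1. For the EGFP contrast in cDC1, simulated over 10700 genes with 50 changed at each fold, edgeR called 0 of 50 at 2-fold, 0 at 4-fold, 18 at 16-fold and 31 at 64-fold, with 3 unchanged genes among 52 called, whereas 179 of 276 genes called by DESeq2 were unchanged. For the same contrast camera with the preset correlation called 20 of 20 lists shifted 4-fold and 6 of 499 unshifted lists, and with an estimated correlation 16 of 20 and 0 of 499. Each gene was drawn independently, so the simulated lists held no inter-gene correlation. These shares of unshifted lists therefore do not give the rate of false list calls in the real libraries, where genes of a list may vary together.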

Results

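Conventional dendritic cells were sorted from MC38-EGFP tumours grown in wild-type mice. MC38 is a mouse colon carcinoma line, and the version used here carries enhanced green fluorescent protein (EGFP), so a dendritic cell that holds tumour-derived EGFP can be separated by flow cytometry from one that does not. The cells were split by subset into cDC1, the subset specialised in presenting antigen of dead cells to CD8 T cells, and cDC2, the subset best known for priming CD4 T cells. Each subset was divided again into an EGFP-positive and an EGFP-negative fraction. The 4 groups held 2 libraries each, 8 in all. The series title concerns sitagliptin, an inhibitor of the peptidase DPP4, and Dpp4 is therefore given in every comparison; the labels name no drug for these libraries. They do not say whether the replicates came from separate animals, so every gene-level p-value measures only the spread between these samples, which may be technical. List p-values compare the genes of a list with all other genes, so a small one reflects agreement among genes and not that spread alone.

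Read counts were given for 24369 gene symbols, and no symbol for EGFP was among them. Library totals ranged from 17869441 to 22195681 counts. The ribosomal RNA precursor Rn45s alone took 26.0%, 28.9%, 30.7%, 35.6%, 26.6%, 19.4%, 24.8% and 31.4% of the counts, in the order EGFP-negative cDC1 replicates 1 and 2, EGFP-positive cDC1 replicates 1 and 2, EGFP-negative cDC2 replicates 1 and 2, and EGFP-positive cDC2 replicates 1 and 2. At least 1 count was found for 8553 and 8208 genes in the EGFP-positive cDC1 libraries, against 9602 to 11922 in the other 6. Replicates differed unequally between groups. Across genes, the Pearson correlation of log2 CPM between the replicates was 0.781 in EGFP-negative cDC1, 0.559 in EGFP-positive cDC1, 0.832 in EGFP-negative cDC2 and 0.800 in EGFP-positive cDC2 (genes are not independent replicates). Of the genes with 100 counts or more in either EGFP-positive cDC1 replicate, 1856 (23.4%) had 0 counts in the other replicate, against 610 (7.49%), 232 (2.81%) and 215 (2.51%) in the other groups. No pair of replicates agreed within sampling noise. Levels below are TMM-scaled CPM (read counts scaled to a common library size), as mean ± SD, with n = 2 libraries per group where a single fraction is compared and n = 4 where fractions are combined. Log2 fold changes carry their standard error.

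Which genes separate the subsets irrespective of EGFP was asked first. Over both EGFP fractions, 150 of 11394 genes differed between cDC1 and cDC2, 93 higher and 57 lower in cDC1. Dpp4, which encodes the target of sitagliptin, stood at 129 ± 65.7 CPM in the 4 cDC1 libraries and 1.85 ± 2.58 CPM in the 4 cDC2 libraries, a log2 fold change of 6.75 ± 1.11 (adjusted p = 0.0264). Cd24a, a surface marker of mouse cDC1, stood at 928 ± 330 against 28.1 ± 7.69 CPM (4.98 ± 0.38, adjusted p = 0.000703). In the opposite direction, Pf4, a chemokine of platelets and tissue macrophages, was at 0.207 ± 0.146 CPM in cDC1 and 625 ± 280 CPM in cDC2 (−11.59 ± 0.54, adjusted p = 2.2e-05). C1qa, a complement component made by macrophages, was at 2.002 ± 1.63 against 1818 ± 639 CPM (−9.85 ± 0.83, adjusted p = 0.00109).

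Among the other genes higher in cDC1 with large fold changes were H2-Oa, a modulator of class II peptide loading (4.88 ± 0.42, adjusted p = 0.00109), Tbc1d8 (5.398 ± 0.58, adjusted p = 0.00251) and Ildr1 (5.71 ± 1.09, adjusted p = 0.039). They also included the metalloprotease gene Adam19 (6.23 ± 1.26, adjusted p = 0.049) and Septin3 (7.78 ± 1.27, adjusted p = 0.0264). Tbx21, which encodes the transcription factor T-bet, averaged 27.5 ± 20.8 CPM in cDC1 with 0 counts in all 4 cDC2 libraries, a level at least 714-fold higher against 3 counts over the group (adjusted p = 0.03). Cacna1s was at least 589-fold higher (adjusted p = 0.0374). B4galt4, a galactosyltransferase gene, was at 28.8 ± 10.1 against 0.0265 ± 0.0306 CPM (adjusted p = 0.00821). Lower in cDC1 were the chemokine gene Ccl8 (0.286 ± 0.420 against 890 ± 916 CPM, adjusted p = 0.0027), the collagenase gene Mmp13 (0.0585 ± 0.0702 against 121 ± 35.5 CPM, adjusted p = 0.00109) and Folr2, a folate receptor of resident macrophages (0.0175 ± 0.0351 against 97.3 ± 78.5 CPM, adjusted p = 0.000194). Cd93 was at 0.0234 ± 0.0467 against 74.8 ± 27.8 CPM (adjusted p = 0.00151). The B-cell adaptor gene Blnk, the lectin gene Fcna and the acute-phase gene Saa3 were lower in cDC1 too, each at adjusted p = 0.00251. Olfml3 and Nxpe5 had 0 counts in all 4 cDC1 libraries and were at least 1010-fold and at least 675-fold lower there (adjusted p = 0.0209 and 0.0222).

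The list of cDC1 identity genes was higher in cDC1 as a group, with a median log2 fold change of 4.01. Of its 20 members tested, 8 were higher by the test over all genes and 18 adjusted over the list alone (camera, adjusted p = 6.27e-26; adjusted p = 0.124 with an estimated correlation). They included Irf8 and Batf3, transcription factors that cDC1 development requires, at 1063 ± 469 against 214 ± 85.2 CPM (2.33 ± 0.42, adjusted p = 0.0346) and 43.9 ± 29.4 against 2.58 ± 1.31 CPM (3.79 ± 0.74, adjusted p = 0.0424). Wdfy4, needed for cross-presentation, had a log2 fold change of 3.88 ± 0.57 (adjusted p = 0.0125), and Ifi205 one of 3.77 ± 0.45 (adjusted p = 0.00435). Xcr1 and Clec9a, the chemokine receptor and the dead-cell receptor by which cDC1 are usually recognised, were at 241 ± 103 against 2.42 ± 2.704 CPM (adjusted p = 0.104) and 144 ± 72.5 against 4.63 ± 4.56 CPM (adjusted p = 0.0557). Both missed the threshold. The list of cDC genes shared by both subsets had a median of 4.28, with 2 of 11 members higher over all genes and 8 adjusted over the list alone (adjusted p = 1.61e-10; adjusted p = 0.124 with an estimated correlation). Flt3, the receptor for the dendritic cell growth factor, was at 129 ± 72.0 CPM in cDC1 and 3.995 ± 5.13 CPM in cDC2 (adjusted p = 0.279). Zbtb46, a transcription factor of the cDC lineage, was at 28.0 ± 12.4 against 0.307 ± 0.492 CPM (adjusted p = 0.0646). Genes of class II presentation were higher with a median of 1.28, 5 of 16 over all genes, and 9 higher and 2 lower adjusted over the list alone (adjusted p = 1.68e-06; adjusted p = 0.241 with an estimated correlation). H2-DMb2 (3.77 ± 0.53, adjusted p = 0.0111), H2-Aa (1.57 ± 0.29, adjusted p = 0.0339) and H2-Ab1 (1.49 ± 0.28, adjusted p = 0.0381) were among them.

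Macrophage and monocyte genes were lower in cDC1, with a median of −5.71 (−3.73 with the 1 member at 0 set to its bound). Of the 22 tested, 3 were lower over all genes and 10 adjusted over the list alone (adjusted p = 1.35e-15; adjusted p = 0.241 with an estimated correlation). The osteopontin gene Spp1, for example, was at 384 ± 346 CPM in cDC1 and 7957 ± 932 CPM in cDC2 (−4.46 ± 0.66, adjusted p = 0.0141). Levels of such genes in the libraries gated as cDC2 were high in both fractions. Lyz2, the lysozyme gene of myeloid cells, was at 20570 ± 2909 CPM in the EGFP-negative and 13880 ± 5193 CPM in the EGFP-positive cDC2 libraries. Apoe, a lipid carrier gene of macrophages, was at 5859 ± 2208 and 5669 ± 2658 CPM. The cDC lineage genes Flt3 and Zbtb46 were low in the same libraries, as given above, so much of their RNA may come from macrophages. The labels do not give the macrophage content of these libraries. Every subset value therefore compares cDC1 with all cells of the cDC2 gate, and cDC2 in these results names that gate. Lysosomal genes were lower in cDC1 with a median of −1.23, 3 of 30 over all genes and 14 adjusted over the list alone, where 1 was higher (adjusted p = 1.54e-07; adjusted p = 0.393 with an estimated correlation). The cathepsin genes Ctsb (−2.53 ± 0.33) and Ctsd (−3.78 ± 0.50), both at adjusted p = 0.00801, and the lysosomal membrane gene Lamp1 (−2.25 ± 0.42, adjusted p = 0.0381) made up the 3. Uptake receptors had a median of −3.02 with 0 of 21 members over all genes and 8 lower and 1 higher adjusted over the list alone (adjusted p = 5.12e-05; adjusted p = 0.319 with an estimated correlation). Cholesterol efflux genes had a median of −2.35, with 1 of 12 lower over all genes and 3 adjusted over the list alone (adjusted p = 0.000693; adjusted p = 0.373 with an estimated correlation). That gene was Plin2, which coats lipid droplets, at 184 ± 37.9 against 940.1 ± 141 CPM (−2.35 ± 0.26, adjusted p = 0.00295). Genes of cDC2 identity had a median of −2.40, with 1 of 19 lower over all genes and 2 adjusted over the list alone (adjusted p = 0.00145; adjusted p = 0.393 with an estimated correlation). That gene was Klf4, a transcription factor needed by part of the cDC2 lineage, at 33.0 ± 24.9 against 151 ± 68.5 CPM (−2.27 ± 0.36, adjusted p = 0.0197). Class I presentation, cholesterol biosynthesis and mregDC genes were higher in cDC1 with medians of 0.18, 0.75 and 0.61, at adjusted p = 0.00206, 0.000266 and 0.00315 (adjusted p = 0.487, 0.393 and 0.524 with an estimated correlation). With each library left out in turn, these medians ranged from 0.077 to 0.487, from 0.037 to 1.281 and from 0.272 to 1.136. The mregDC list holds genes of mature regulatory dendritic cells, a migratory state with Ccr7 and immune checkpoint ligands. Glycolysis and hypoxia genes were lower with a median of −1.01 (adjusted p = 0.00979; adjusted p = 0.587 with an estimated correlation). This pools a lower list in EGFP-negative cells (median −2.42) with one tested upward in EGFP-positive cells (median 0.33). Within that list Pfkp, a phosphofructokinase gene, was higher over all genes at 526 ± 79.3 against 130 ± 66.0 CPM (2.16 ± 0.28, adjusted p = 0.00801), and the angiogenic factor gene Vegfa lower at 16.7 ± 17.8 against 112 ± 41.6 CPM (−3.40 ± 0.60, adjusted p = 0.03).

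The median over all genes was −0.285 with TMM scaling. By DESeq2 the same comparison gave 1160 genes, 396 higher and 764 lower in cDC1. Without each library in turn, in the order given above for Rn45s, the edgeR count was 69, 67, 263, 277, 68, 50, 86 and 88. Of the 12 lists, 8 kept their call without any 1 library. The call was lost in 1 of 8 such fits for mregDC, class I presentation and cholesterol biosynthesis genes, and in 4 for glycolysis and hypoxia.

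**Figure D1:**
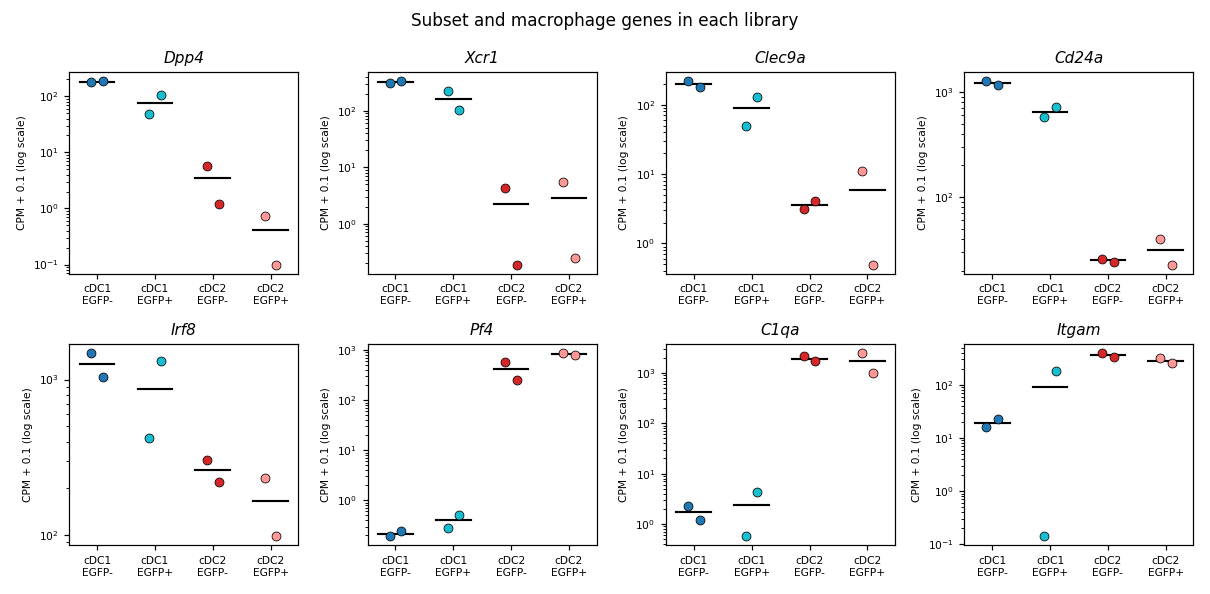
Level (CPM + 0.1, log scale) of 8 genes in the 8 libraries, with dots for single libraries and bars for group means; groups are cDC1 and cDC2, EGFP-negative and EGFP-positive. Dpp4, Xcr1, Clec9a, Cd24a and Irf8 stand higher in the cDC1 groups, Pf4 and C1qa higher in the cDC2 groups, and Itgam lies at 0.0438 and 181 CPM in the EGFP-positive cDC1 replicates.

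Within the EGFP-negative cells, the subsets were then compared in the model of all 8 libraries, so that the EGFP-positive libraries also entered the filter, the scaling and the spread. Of 11394 genes, 41 differed, 13 higher and 28 lower in cDC1. Cystatin C (Cst3), an abundant cDC1 transcript, was at 27630 ± 5857 CPM in cDC1 and 1144 ± 45.3 CPM in cDC2 (4.60 ± 0.44, adjusted p = 0.0281). Cd24a was at 1207 ± 72.6 against 25.1 ± 1.18 CPM (5.59 ± 0.41, adjusted p = 0.00843). Lower in cDC1 were Pf4 at 0.117 ± 0.0328 against 415 ± 234 CPM (−11.72 ± 0.79, adjusted p = 0.00843) and C1qa at 1.66 ± 0.762 against 1907 ± 268 CPM (−10.16 ± 1.28, adjusted p = 0.0323). Dpp4 was at 182 ± 2.45 CPM in cDC1 and 3.39 ± 3.21 CPM in cDC2, a log2 fold change of 5.75 ± 1.41 that missed the threshold here (adjusted p = 0.2).

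Further genes higher in EGFP-negative cDC1 were the proapoptotic gene Pmaip1 (3.63 ± 0.40, adjusted p = 0.0287) and the G protein subunit gene Gng10 (3.31 ± 0.35, adjusted p = 0.0287). They also included Gcnt2 (3.38 ± 0.49, adjusted p = 0.0475), Anxa6 (2.75 ± 0.34, adjusted p = 0.0323), Wdfy4 (4.81 ± 0.68, adjusted p = 0.0467), H2-Oa (4.42 ± 0.49, adjusted p = 0.0287) and Tbc1d8 (6.08 ± 0.76, adjusted p = 0.0323). Rin2, Tmem171 and Folr2 had 0 counts in both cDC1 libraries and were at least 825-fold, at least 661-fold and at least 444-fold lower (adjusted p = 0.0323, 0.0323 and 0.0287). Dusp6, a phosphatase that restrains ERK signalling, was at 0.0467 ± 0.0661 against 82.5 ± 24.5 CPM (adjusted p = 0.0287), and Mmp13 at 0.0467 ± 0.0661 against 149 ± 23.8 CPM (adjusted p = 0.029). Rnase4, a secreted ribonuclease gene whose first exons are shared with Ang, so that its counts are uncertain, was at 0.0467 against 115 ± 17.5 CPM (adjusted p = 0.016). Tmem37 (adjusted p = 0.029) and Cd93 (adjusted p = 0.0467) were likewise lower in cDC1.

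As a group, cDC1 identity genes were higher (median 4.78), 2 of 20 over all genes and 15 adjusted over the list alone (camera, adjusted p = 1.65e-18; adjusted p = 0.291 with an estimated correlation). Glycolysis and hypoxia genes were lower in EGFP-negative cDC1 than in EGFP-negative cDC2 (median −2.42), 4 of 21 over all genes, and 15 lower and 1 higher adjusted over the list alone (adjusted p = 9.1e-13). It was the one list of this comparison whose call held with an estimated correlation (adjusted p = 0.0349). The 4 genes were the glycolytic enzyme genes Tpi1 (180.3 ± 40.3 against 953 ± 6.31 CPM, −2.40 ± 0.32, adjusted p = 0.0439) and Pkm (848 ± 127 against 3593 ± 334 CPM, −2.08 ± 0.30, adjusted p = 0.0468) and 2 more. These were the lactate exporter gene Slc16a3 (35.7 ± 4.23 against 269 ± 33.1 CPM, −2.92 ± 0.40, adjusted p = 0.0457) and Vegfa (3.27 ± 1.99 against 75.7 ± 4.42 CPM, −4.53 ± 0.63, adjusted p = 0.0467). Lysosomal genes were lower (median −1.46), 4 of 30 over all genes and 14 adjusted over the list alone (adjusted p = 7.92e-11; adjusted p = 0.291 with an estimated correlation). Ctsl was at 11.4 ± 0.638 against 1959 ± 771 CPM (−7.43 ± 0.89, adjusted p = 0.029). Macrophage genes were lower as well (median −5.80), 2 of 22 over all genes and 12 adjusted over the list alone (adjusted p = 1.49e-11; adjusted p = 0.291 with an estimated correlation). Uptake receptors had a median of −3.75, with 1 of 21 lower over all genes, and 9 lower and 1 higher adjusted over the list alone (adjusted p = 0.00012; adjusted p = 0.291 with an estimated correlation). The endocytic receptor gene Lrp1 was that gene, at 1.87 ± 0.202 against 132 ± 14.9 CPM (−6.14 ± 0.67, adjusted p = 0.0287). Inflammatory cytokine and NF-kB genes had a median of −1.84 with 0 of 24 members over all genes and 4 lower adjusted over the list alone (adjusted p = 0.000825; adjusted p = 0.291 with an estimated correlation). Their members Tnfaip3, a feedback inhibitor of NF-kB, and Cxcl2, a neutrophil chemokine, were at 23.9 ± 7.57 against 118 ± 18.5 CPM (adjusted p = 0.0691) and 22.8 ± 4.07 against 1741 ± 225 CPM (adjusted p = 0.181). A further 6 lists passed, namely shared cDC genes, class II presentation, cholesterol efflux, oxidative phosphorylation, cDC2 identity and class I presentation, at adjusted p from 1.97e-06 to 0.0448, and from 0.291 to 0.808 with an estimated correlation.

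DESeq2 gave 838 genes, 277 higher and 561 lower in cDC1, and voom with library quality weights gave 528. An edgeR fit of the 4 EGFP-negative libraries only gave 292, 106 higher and 186 lower. Without each library in turn, in the same order, the edgeR count was 4, 1, 465, 413, 1, 2, 56 and 56. Of the 12 lists, 9 kept their call without any 1 library. It was lost in 1 of 8 such fits for cDC2 identity, 2 for oxidative phosphorylation and 6 for class I presentation.

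In EGFP-positive cells, 26 genes differed between the subsets, 13 higher and 13 lower in cDC1. Cd83, a surface marker of mature dendritic cells, was at 996 ± 298 CPM in cDC1 and 154 ± 15.1 CPM in cDC2 (2.698 ± 0.35, adjusted p = 0.0401). Herpud1, a gene of the endoplasmic reticulum stress response, was at 510 ± 127 against 38.0 ± 7.38 CPM (3.75 ± 0.42, adjusted p = 0.0339). The proliferation genes Birc5 and Aurkb, which act at mitosis, were lower in cDC1, at 0.0438 ± 0.0619 against 39.1 ± 23.2 CPM (adjusted p = 0.0339) and 0.0570 ± 0.0187 against 21.2 ± 11.8 CPM (adjusted p = 0.0401). Dpp4 was at 75.9 ± 39.3 against 0.312 ± 0.442 CPM (7.91 ± 1.59) and missed the threshold (adjusted p = 0.102).

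Other genes higher in EGFP-positive cDC1 were H2-Oa (5.35 ± 0.52, adjusted p = 0.0253), Cd24a (4.38 ± 0.38, adjusted p = 0.0223) and the actin cytoskeleton genes Cnn2 (3.77 ± 0.33, adjusted p = 0.0223), Lsp1 (3.40 ± 0.46, adjusted p = 0.0467) and Zyx (3.19 ± 0.40, adjusted p = 0.0401). They also included Syngr2 (3.67 ± 0.39, adjusted p = 0.0297) and Cst3 (3.56 ± 0.42, adjusted p = 0.0378). Pfkp was at 460.2 ± 35.2 against 73.7 ± 3.86 CPM (2.64 ± 0.28, adjusted p = 0.0295). Cd93, the myeloid transcription factor gene Cebpa and the phosphatase gene Ptpn12 had 0 counts in both EGFP-positive cDC1 libraries and were at least 1100-fold, at least 737-fold and at least 670-fold lower (adjusted p = 0.0401, 0.0401 and 0.0378). Pf4 was at 0.298 ± 0.174 against 834 ± 71.4 CPM (−11.47 ± 0.77, adjusted p = 0.00941) and Ccl8 at 0.478 ± 0.614 against 1680 ± 119 CPM (−11.85 ± 1.54, adjusted p = 0.0401). The interleukin-7 receptor gene Il7r was at 0.325 ± 0.335 against 217 ± 2.07 CPM (−9.45 ± 1.23, adjusted p = 0.0401), and C1qa at 2.35 ± 2.64 against 1729 ± 1059 CPM (−9.54 ± 1.25, adjusted p = 0.0405). Folr2 (adjusted p = 0.0284), Hgsnat (adjusted p = 0.0284) and Mmp13 (adjusted p = 0.0401) were also lower.

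The cDC1 identity list was higher (median 3.62), 1 of 20 over all genes and 13 adjusted over the list alone (camera, adjusted p = 1.68e-17; adjusted p = 0.466 with an estimated correlation). The mregDC genes were higher with a median of 1.07, 0 of 25 over all genes and 6 adjusted over the list alone (adjusted p = 9.68e-05; adjusted p = 0.506 with an estimated correlation). With each library left out in turn, that median ranged from 0.27 to 2.62. The EGFP-positive cDC1 replicates lay far apart in this list: Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 368 and 5498 CPM, and Il12b, a subunit of interleukin-12, at 25.3 and 4651 CPM. Cholesterol biosynthesis genes were higher with a median of 1.34, 0 of 21 over all genes and 1 adjusted over the list alone (adjusted p = 2.03e-06; adjusted p = 0.499 with an estimated correlation). Proliferation genes were lower with a median of −6.33 (−4.43 with the 5 members at 0 set to their bounds), 2 of 24 over all genes and 11 adjusted over the list alone (adjusted p = 0.00491; adjusted p = 0.506 with an estimated correlation). Macrophage genes were lower, with a median of −7.33 (−2.75 with the 1 member at 0 set to its bound), 2 of 22 over all genes and 7 adjusted over the list alone (adjusted p = 2.03e-06; adjusted p = 0.506 with an estimated correlation). With each library left out in turn, the macrophage median ranged from −10.79 to −1.66. For glycolysis and hypoxia the median was 0.33 and the test upward, while the mean was −0.51, and adjusted over the list alone 4 of 21 were higher and 3 lower (adjusted p = 0.0225; adjusted p = 0.466 with an estimated correlation). For class I presentation the median was −0.02 while the mean was 0.37 and the test upward, with 0 of 17 over all genes and 3 higher adjusted over the list alone (adjusted p = 0.00111; adjusted p = 0.506 with an estimated correlation). A further 5 lists passed, upward for shared cDC genes and class II presentation and downward for cDC2 identity, uptake receptors and lysosome, at adjusted p from 2.85e-07 to 0.0333, and from 0.466 to 0.629 with an estimated correlation.

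The median over all genes was −0.305 with TMM scaling. DESeq2 gave 1586 genes, 461 higher and 1125 lower in cDC1, voom gave 22 and a model of the 4 compared libraries alone gave 0. Without each library in turn, in the same order, the edgeR count was 19, 19, 847, 1273, 1, 1, 13 and 1. Of the 12 lists, 5 kept their call without any 1 library, namely cDC1 identity, shared cDC, class II presentation, cholesterol biosynthesis and macrophage genes. It was lost in 1 of 8 such fits for mregDC and proliferation genes and in 2 for cDC2 identity, class I presentation and uptake receptors. It was lost in 6 for lysosome (median −0.48 to −1.35) and in 7 for glycolysis and hypoxia (median −0.07 to 0.48).

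The central question of the sort was how EGFP-positive cells differ from EGFP-negative ones. Uptake of tumour material itself was not measured in these counts, which hold no EGFP symbol. In cDC1, glycolysis and hypoxia genes were higher in EGFP-positive cells as a list, with a median log2 fold change of 1.99 (camera, adjusted p = 2.71e-13), and this call held with an estimated correlation (adjusted p = 0.0344). Proliferation genes were lower, with a median of −6.19 (−4.28 with the 5 members at 0 set to their bounds; adjusted p = 1.27e-06; adjusted p = 0.67 with an estimated correlation). No single gene passed edgeR's test: 0 of 11394 had an adjusted p under the threshold, with 1452 at an unadjusted p under 0.05, 496 of them higher and 956 lower, and the smallest adjusted p was 0.0581. DESeq2 gave 1325 genes and voom 0. Dpp4 was at 75.9 ± 39.3 CPM in EGFP-positive and 182 ± 2.45 CPM in EGFP-negative cDC1, a log2 fold change of −1.27 ± 1.17 (adjusted p = 0.674).

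Of the 21 glycolysis and hypoxia genes tested, 18 had positive and 2 negative fold changes, and 12 were higher adjusted over the list alone, against 0 over all genes. Pfkl, a phosphofructokinase gene, was at 186 ± 2.33 CPM in EGFP-positive and 26.9 ± 3.31 CPM in EGFP-negative cells (2.79 ± 0.35, adjusted p = 0.0793). Slc16a3 was at 262 ± 95.1 against 35.7 ± 4.23 CPM (2.88 ± 0.40, adjusted p = 0.0793). Tpi1 was at 782 ± 206 against 180.3 ± 40.3 CPM (2.12 ± 0.32, adjusted p = 0.0818) and Pkm at 2968 ± 655 against 848 ± 127 CPM (1.81 ± 0.30, adjusted p = 0.114). Of the 24 proliferation genes, 12 were lower adjusted over the list alone, against 0 over all genes. Birc5 was at 0.0438 ± 0.0619 against 81.4 ± 2.17 CPM (adjusted p = 0.0581) and Aurkb at 0.0570 ± 0.0187 against 37.9 ± 5.83 CPM (adjusted p = 0.0777). The cyclin gene Ccnb1 was at 0.0351 ± 0.0496 against 38.3 ± 19.0 CPM (adjusted p = 0.0805) and the spindle gene Tpx2 at 0.0438 ± 0.0619 against 19.0 ± 1.19 CPM (adjusted p = 0.141). These 4 genes rest on fewer than 4 counts over the EGFP-positive cDC1 group, which also had the fewest genes detected.

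Besides these, the genes of smallest p that stood higher in EGFP-positive cDC1 were Dusp6 (115 ± 68.6 against 0.0467 ± 0.0661 CPM, adjusted p = 0.0581) and Wls, a carrier for secreted Wnt proteins (41.9 ± 21.4 against 0.0700 ± 0.0331 CPM, adjusted p = 0.0581). They also included Rnase4 (21.7 ± 17.1 against 0.0467 CPM, adjusted p = 0.0581) and the kinesin gene Kif3a (28.5 ± 4.52 against 0.0467 CPM, adjusted p = 0.0793). Dusp6 and Rnase4 also stood higher in the cDC2 gate than in cDC1 among EGFP-negative cells, as given above. Whether RNA of that gate brought them in was not tested gene by gene. On the lower side were Asf1b, a histone chaperone gene of dividing cells, at 0 counts against 60.9 ± 34.1 CPM, at least 769-fold lower (adjusted p = 0.0793), and Nagpa at 0 counts against 27.5 ± 8.83 CPM, at least 347-fold lower (adjusted p = 0.0793). Arhgap18 was at 1.80 ± 1.35 against 110 ± 7.34 CPM (−5.91 ± 0.80, adjusted p = 0.0793). None of them passed.

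A further 7 lists passed with the preset correlation in cDC1, none with an estimated correlation. Cholesterol biosynthesis genes were higher with a median of 1.26, 20 of 21 positive, 0 over all genes and 1 adjusted over the list alone (adjusted p = 5.52e-05; adjusted p = 0.67 with an estimated correlation). Fdps, an enzyme gene of the mevalonate pathway, was at 800 and 184 CPM in the 2 EGFP-positive replicates against 178 ± 68.7 CPM in EGFP-negative cells (adjusted p = 0.396). The list median was 0.13 without EGFP-positive cDC1 replicate 1 (adjusted p = 0.217). The mregDC list was higher with a median of 0.70 (1.32 with the 1 member at 0 set to its bound), 0 of 25 over all genes and 1 adjusted over the list alone (adjusted p = 0.00363; adjusted p = 0.696 with an estimated correlation). Relb, a subunit of non-canonical NF-kB, was at 155 ± 107 against 17.2 ± 0.131 CPM (3.17 ± 0.63, adjusted p = 0.15). Cd274, which encodes PD-L1, was at 425 ± 203 against 144 ± 64.3 CPM (1.56 ± 0.63, adjusted p = 0.365). The mregDC median was −0.34 without EGFP-positive cDC1 replicate 2 (adjusted p = 0.842) and 0.28 without EGFP-negative cDC1 replicate 2 (adjusted p = 0.123).

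Identity genes of cDC1 were lower in EGFP-positive cDC1 with a median of −0.97, 17 of 20 negative and 0 called, over all genes or adjusted over the list alone (adjusted p = 0.00551; adjusted p = 0.696 with an estimated correlation). Xcr1 was at 163 ± 83.6 against 320.3 ± 15.4 CPM (adjusted p = 0.867) and Clec9a at 89.3 ± 56.9 against 198 ± 27.1 CPM (adjusted p = 0.712). Batf3 was at 18.5 ± 3.10 against 69.2 ± 3.57 CPM (adjusted p = 0.385) and Naaa, an acid amidase gene, at 1354 ± 268 against 3422 ± 497 CPM (adjusted p = 0.291). The list median was −0.98 without EGFP-negative cDC1 replicate 1, where the call was lost (adjusted p = 0.0881). NF-kB and inflammatory genes were higher with a median of 0.86 (1.20 with the 1 member at 0 set to its bound), 0 of 24 over all genes and 2 adjusted over the list alone (adjusted p = 0.0098; adjusted p = 0.67 with an estimated correlation). Tnfaip3 was at 99.6 ± 15.0 against 23.9 ± 7.57 CPM (adjusted p = 0.14) and Nfkbia, the NF-kB inhibitor gene, at 1062 ± 476 against 141 ± 72.2 CPM (adjusted p = 0.15). Oxidative phosphorylation genes were lower (median −0.60, 0 of 25 over all genes or adjusted over the list alone, adjusted p = 0.0272; adjusted p = 0.67 with an estimated correlation). Lysosomal genes had a median of 0.21 with 1 of 30 adjusted over the list alone (adjusted p = 0.0391; adjusted p = 0.853 with an estimated correlation). That member was Ctsl, at 634 ± 582 against 11.4 ± 0.638 CPM (adjusted p = 0.0793 over all genes). In EGFP-positive cDC1 replicates 1 and 2 Ctsl was at 1045 and 222 CPM, and in EGFP-positive cDC2 at a mean of 2237 CPM. Immediate early and dissociation stress genes, which rise when tissue is digested, were higher with a median of 0.61, 0 of 20 over all genes and 2 adjusted over the list alone (adjusted p = 0.0354; adjusted p = 0.671 with an estimated correlation). Without EGFP-positive cDC1 replicate 2 the calls for NF-kB (median −0.04), oxidative phosphorylation (−0.47), lysosome (−0.18) and stress genes (0.52) were lost. In all, the call was lost in 3, 3, 5 and 2 of the 8 fits without 1 library.

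The EGFP-positive cDC1 replicates stood apart from each other in genes of other cells. Itgam was at 0.0438 CPM in replicate 1 and 181 CPM in replicate 2, Arg1 at 1.27 and 1362 CPM and Apoe at 1.31 and 1543 CPM. Cd14 was at 1.18 and 831 CPM, Csf1r at 1.27 and 401 CPM, and Lyz2 at 290.2 and 8773 CPM. The matrix gene Sparc was at 674 CPM in replicate 1 and 0.140 CPM in replicate 2, Col6a1 at 176 and 9.90 CPM, and Cav1 at 177 and 0.0702 CPM. In the EGFP-negative cDC1 libraries Sparc was at 4.08 ± 0.833 CPM. As lists, macrophage genes (median 0.21, mean −0.17), fibroblast and endothelial genes (median 2.88) and epithelial carcinoma genes (median 1.20) passed no test in this comparison (adjusted p = 0.692, 0.119 and 0.389). Fold changes were positive for 18 of 22, 7 of 9 and 6 of 10 of their members. As ratios of group means the medians were 1.35, 4.94 (1 member at 0 set to its bound) and 3.27 (3 members). Without EGFP-positive cDC1 replicate 1 edgeR gave 763 genes, and without replicate 2 of that group 1050, against 0 without any other library. The number of lists passing was 9, and 5, 5, 13, 4, 8, 8, 10 and 9 without each library in the same order.

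**Figure D2:**
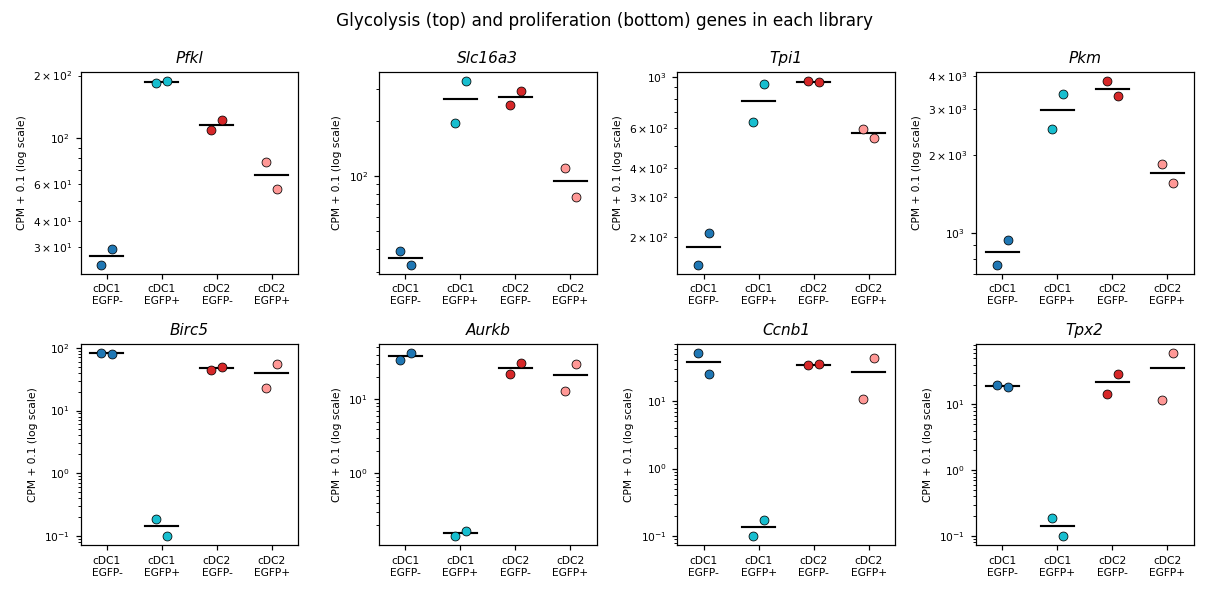
Level (CPM + 0.1, log scale) of 4 glycolysis genes (Pfkl, Slc16a3, Tpi1, Pkm) and 4 proliferation genes (Birc5, Aurkb, Ccnb1, Tpx2) in the 8 libraries, with dots for single libraries and bars for group means. Pfkl averages 186 CPM in EGFP-positive and 26.9 CPM in EGFP-negative cDC1, and Birc5 0.0438 against 81.4 CPM.

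In cDC2 the same split gave 0 of 11394 genes by edgeR, with 300 at an unadjusted p under 0.05, 125 higher and 175 lower in EGFP-positive cells, and a smallest adjusted p of 1. DESeq2 gave 110 genes and voom 2. Glycolysis and hypoxia genes were lower in EGFP-positive cDC2 as a list, with a median of −0.51, 15 of 21 negative, 0 over all genes and 3 adjusted over the list alone (camera, adjusted p = 3.85e-06; adjusted p = 0.132 with an estimated correlation). Class II presentation genes were lower with a median of −0.79 (adjusted p = 0.000757; adjusted p = 0.754 with an estimated correlation). Dpp4 was at 0.312 ± 0.442 CPM in EGFP-positive and 3.39 ± 3.21 CPM in EGFP-negative cDC2 (−3.42 ± 1.34, adjusted p = 1).

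Pfkp was at 73.7 ± 3.86 against 186 ± 19.1 CPM (−1.34 ± 0.27). Slc16a3 was at 93.5 ± 23.2 against 269 ± 33.1 CPM (−1.53 ± 0.38) and Pkm at 1700 ± 200.4 against 3593 ± 334 CPM (−1.08 ± 0.29). Of the class II list, H2-DMb1, which helps load peptides, was at 234 ± 125 against 561 ± 92.3 CPM and H2-Aa at 4448 ± 1949 against 7718 ± 1194 CPM. Of its 16 members 0 were called over all genes or adjusted over the list alone. Lysosomal genes were lower with a median of −0.46, 22 of 30 negative (adjusted p = 0.000284; adjusted p = 0.805 with an estimated correlation). The hexosaminidase gene Hexa was at 219 ± 65.1 against 572 ± 65.9 CPM. NF-kB and inflammatory genes were lower with a median of −0.44, 18 of 24 negative (adjusted p = 0.0283; adjusted p = 0.773 with an estimated correlation). Il1b, which encodes interleukin-1 beta, was at 1676 ± 165 against 5350 ± 1166 CPM. Class I presentation (median −0.40, adjusted p = 0.0132; adjusted p = 0.805 with an estimated correlation) and shared cDC genes (median −0.74, adjusted p = 0.0208; adjusted p = 0.773 with an estimated correlation) were lower too. So was the dipeptidyl peptidase family (median −0.80, 8 of 8 negative, adjusted p = 0.046; adjusted p = 0.754 with an estimated correlation). Stress genes were higher with a median of 0.72, 15 of 20 positive (adjusted p = 0.00626; adjusted p = 0.754 with an estimated correlation). Egr1 was at 211 ± 49.9 against 50.04 ± 24.1 CPM and Atf3 at 400 ± 147 against 150 ± 6.87 CPM. Adjusted over the list alone, 0 members of these last 6 lists were called. With each library left out in turn, the median ranged from −0.99 to −0.044 for lysosome and from −0.84 to 0.058 for class I presentation. For shared cDC genes it ranged from −1.34 to −0.23. Without any 1 library glycolysis and hypoxia kept its call, and each of the other 7 lists lost it in 1 to 3 of 8 such fits.

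The genes of smallest p higher in EGFP-positive cDC2, all at adjusted p = 1, were Wfdc17, a myeloid secreted protein gene (764 ± 173 against 242 ± 68.3 CPM, 1.66 ± 0.34), the cyclin gene Ccnl1 (1.72 ± 0.39), Rtn4 (1.58 ± 0.37), the AP-1 gene Jund (1.83 ± 0.45) and Gnas (1.25 ± 0.32). On the lower side they were Tmem109 (38.4 ± 2.32 against 129 ± 8.61 CPM, −1.75 ± 0.31), Pfkp, Xab2 (−2.71 ± 0.57), the phosphatase gene Ptpn6 (−1.47 ± 0.33) and the NF-kB inhibitor gene Nfkbie (−1.58 ± 0.35). Macrophage genes stood high in both fractions: C1qa was at 1729 ± 1059 CPM in EGFP-positive and 1907 ± 268 CPM in EGFP-negative cDC2, with Flt3 at 2.60 ± 3.61 and 5.39 ± 7.62 CPM. The number of lists passing was 8, and it was 4 without EGFP-negative cDC2 replicate 1 and 3 without EGFP-positive cDC2 replicate 2.

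Whether the EGFP difference itself differed between the subsets was tested as an interaction, the cDC1 difference minus the cDC2 difference. The glycolysis and hypoxia list had an interaction median of 2.47 with 20 of 21 members positive (camera, adjusted p = 1.5e-18), and the call held with an estimated correlation (adjusted p = 0.0153). Adjusted over the list alone, 13 of its members were higher and 1 lower, against 0 over all genes. Slc16a3 had an interaction of 4.40 ± 0.55 (adjusted p = 0.141), and Pfkl, Pkm and Tpi1 had 3.59 ± 0.47, 2.89 ± 0.41 and 2.86 ± 0.44 (all at adjusted p = 0.154). By edgeR, 0 of 11394 genes passed, with 1180 at an unadjusted p under 0.05, 363 positive and 817 negative; DESeq2 gave 714 genes and voom 1. The median over all genes was −0.20 with TMM and −0.06 with RLE scaling.

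Proliferation genes had an interaction median of −6.12, 21 of 24 negative and 10 lower adjusted over the list alone (adjusted p = 3.53e-05; adjusted p = 0.731 with an estimated correlation). The genes of smallest p on that side were Birc5 (adjusted p = 0.141), Aurkb, Asf1b, Ptpn12 and Hgsnat (each at adjusted p = 0.154), and on the positive side Dusp6, Wls and Rnase4 (each at adjusted p = 0.141). In each of them at least 1 group had fewer than 4 counts in all, so no fold change is given. Lysosomal genes had an interaction median of 0.78 with 1 of 30 adjusted over the list alone (adjusted p = 3.53e-05; adjusted p = 0.731 with an estimated correlation), and it ranged from 0.31 to 1.375 without EGFP-positive cDC2 replicates 2 and 1. Cholesterol biosynthesis genes had one of 1.55 with 19 of 21 positive and 0 adjusted over the list alone (adjusted p = 0.000734; adjusted p = 0.731 with an estimated correlation), and one of 0.024 without EGFP-positive cDC1 replicate 1 (adjusted p = 0.216). NF-kB and inflammatory genes had 1.46 with 0 of 24 adjusted over the list alone (adjusted p = 0.00212; adjusted p = 0.731 with an estimated correlation). The mregDC genes had 1.04 with 1 of 25 (adjusted p = 0.00324; adjusted p = 0.731 with an estimated correlation). Without EGFP-positive cDC1 replicate 2 the mregDC value was 0.58 (adjusted p = 0.369), and the calls for lysosome, NF-kB and proliferation were also lost (adjusted p = 0.0711, 0.0578 and 0.0711). Without EGFP-negative cDC1 replicate 2 the mregDC value was 0.67 (adjusted p = 0.0769). Nfkbia had an interaction of 3.10 ± 0.76 (adjusted p = 0.332) and Relb one of 3.98 ± 0.85 (adjusted p = 0.302). Dpp4 had one of 2.15 ± 1.71 (adjusted p = 0.714). The count of genes was 515 without EGFP-positive cDC1 replicate 1, 668 without EGFP-positive cDC1 replicate 2 and 0 without any other library. The count of lists was 11 without EGFP-positive cDC1 replicate 1, 2 without EGFP-positive cDC1 replicate 2 and 10 without EGFP-positive cDC2 replicate 1.

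With subset as a covariate, the EGFP difference averaged over cDC1 and cDC2 was tested with 4 libraries a side. It gave 8 lists. Of 34 splits of the libraries into 4 and 4, the real one included, 15 gave at least as many, so chance cannot be excluded for their number. Stress genes were higher in EGFP-positive cells as a list, with a median of 0.57, 14 of 20 positive and 1 higher adjusted over the list alone (camera, adjusted p = 0.000249; adjusted p = 0.168 with an estimated correlation). Egr1, an immediate early transcription factor gene, was at 151 ± 78.4 CPM in EGFP-positive and 28.7 ± 28.6 CPM in EGFP-negative cells (2.83 ± 0.60, adjusted p = 0.951). Cholesterol biosynthesis genes were higher with a median of 0.65, 19 of 21 positive (adjusted p = 0.000599; adjusted p = 0.513 with an estimated correlation). In cDC2 alone their median was −0.04, with 12 positive and 9 negative (adjusted p = 0.639), and without EGFP-positive cDC1 replicate 1 the call over both subsets was lost (median 0.17, adjusted p = 0.859). By edgeR 0 of 11394 genes passed, with 595 at an unadjusted p under 0.05, 351 higher and 244 lower, and a smallest adjusted p of 0.951; DESeq2 gave 184 genes and voom 4.

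Genes of cDC1 identity were lower with a median of −0.94, 16 of 20 negative (adjusted p = 3.14e-06; adjusted p = 0.513 with an estimated correlation). In cDC2 alone their median was −0.31 (adjusted p = 0.0923), and over both subsets it was −0.55 without EGFP-positive cDC1 replicate 1. Proliferation genes were lower with a median of −1.73, 22 of 24 negative (adjusted p = 2.26e-05; adjusted p = 0.513 with an estimated correlation). In cDC2 alone their median was −0.39, with 13 positive and 11 negative (adjusted p = 0.0564). Over both subsets it ranged from −3.58 (without EGFP-positive cDC2 replicate 2) to −1.02 (without EGFP-positive cDC1 replicate 2). Rrm2, a ribonucleotide reductase subunit gene, was at 17.2 ± 10.01 against 69.1 ± 13.1 CPM (−2.00 ± 0.52, adjusted p = 0.951). Class II presentation genes were lower with a median of −0.53, 12 of 16 negative (adjusted p = 0.000249; adjusted p = 0.513 with an estimated correlation). Shared cDC genes (median −0.64) and oxidative phosphorylation genes (median −0.20) were lower, both at adjusted p = 0.0234, and at adjusted p = 0.513 with an estimated correlation. In cDC2 alone the oxidative phosphorylation median was 0.11 (mean −0.05, adjusted p = 0.676). The call for shared cDC genes was lost without EGFP-positive cDC1 replicate 1 (adjusted p = 0.508) and with the 10 CPM filter (adjusted p = 0.061). That for oxidative phosphorylation was lost without EGFP-negative cDC1 replicate 1 (adjusted p = 0.0625) or EGFP-positive cDC1 replicate 2 (adjusted p = 0.0737). Sdha, a subunit of succinate dehydrogenase, was at 90.8 ± 25.5 against 184 ± 32.3 CPM (−1.06 ± 0.29, adjusted p = 0.951). Glycolysis and hypoxia genes were higher with a median of 0.43 (adjusted p = 0.0134; adjusted p = 0.754 with an estimated correlation), although the list was higher in cDC1 and lower in cDC2 when these were tested apart. Its call was lost without any 1 of the 4 cDC1 libraries (medians 0.17 to 0.25, adjusted p from 0.0976 to 0.508). In these lists and for cholesterol biosynthesis 0 members were called over all genes or adjusted over the list alone.

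The genes of smallest p were, on the higher side, Ltbp4, Bgn, Mpzl2, Map1b and Cald1. Bgn, a matrix proteoglycan gene, was at 83.5 ± 125 against 0.121 ± 0.0355 CPM, and Ltbp4 at 51.4 ± 65.1 against 0.0228 ± 0.0263 CPM. Mpzl2 was at 21.1 ± 31.6 CPM against 0 counts, at least 590-fold higher. All were at adjusted p = 0.951. The list of fibroblast and endothelial genes did not pass (median 0.27, adjusted p = 0.0674; adjusted p = 0.513 with an estimated correlation). On the lower side they were Isyna1 (−1.80 ± 0.36), Acaa2 (−1.91 ± 0.46), Cpsf3 (−1.76 ± 0.45), Rrm2 and Sdf2l1 (−1.08 ± 0.29), at the same adjusted p. Dpp4 was at 38.1 ± 49.2 against 93.0 ± 103 CPM (−2.25 ± 0.93, adjusted p = 0.951). The number of lists passing was 8, and 13 without EGFP-positive cDC2 replicate 1.

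The positions of the genes followed most closely were taken from the GRCm38 annotation, which matches the mm10 build in the submitters' processing notes. Dpp4 lies on chromosome 2 from 62330073 to 62412231 on the minus strand, with Gm13561 annotated on the other strand. Cd24a lies on chromosome 10 from 43578284 to 43584265, Irf8 on chromosome 8 from 120736358 to 120756694, Pf4 on chromosome 5 from 90772435 to 90773383 and C1qa on chromosome 4 from 136895917 to 136898803. Pfkl lies on chromosome 10 from 77986947 to 78010083, Slc16a3 on chromosome 11 from 120948480 to 120960868 and Birc5 on chromosome 11 from 117849251 to 117855743. H2-Oa shares its position with BC051537 and Folr2 with Gm10602 on the other strand, and Clec9a overlaps Clec1b on the same strand. Use of strand in the counting is not given in the sources used here, so reads of such overlapping pairs cannot be told apart in these counts.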

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

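The tests for cells of the cDC2 gate in the EGFP-positive cDC1 libraries, and the test for mature cells in replicate 2 of that group, were chosen only after the marker levels of those libraries had been seen. For 6 gene lists, the EGFP difference in cDC1 differed from that in cDC2 by the interaction test. The interaction medians were 2.47 for glycolysis and hypoxia, −6.12 for proliferation, 0.783 for lysosome, 1.55 for cholesterol biosynthesis, 1.46 for NF-kB and inflammatory genes and 1.04 for mregDC genes. With an estimated correlation, glycolysis and hypoxia held (adjusted p = 0.0153) and the other 5 were lost (each at adjusted p = 0.731). The interaction call for cholesterol biosynthesis was lost without EGFP-positive cDC1 replicate 1 (median 0.024, adjusted p = 0.216). Without replicate 2 those for mregDC (0.58, adjusted p = 0.369), lysosome (0.36, adjusted p = 0.0711), NF-kB and inflammatory genes (0.80, adjusted p = 0.0578) and proliferation (−7.78, adjusted p = 0.0711) were lost.

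Glycolysis and hypoxia genes were higher in EGFP-positive cDC1 in both libraries, with medians of 1.515 in replicate 1 and 1.722 in replicate 2 against the EGFP-negative cDC1 mean. The list's median lay above those of all 10000 random lists of matched expression (percentile 100). This argues against loss or gain of transcripts that falls on genes at random. Such lists hold unrelated genes, so they cannot speak to genes of this list varying together in a library. Camera had called the list on the same libraries, so the percentile is no separate support. Cells of the cDC2 gate expressed these genes more strongly than EGFP-negative cDC1, while EGFP-positive cDC1 against EGFP-positive cDC2 gave a median of 0.33 and a mean of −0.51 (adjusted p = 0.0225; adjusted p = 0.466 with an estimated correlation). In EGFP-positive cDC1 replicates 1 and 2, 7 and 6 of the 21 genes lay above both cDC2 groups. In replicate 1, genes abundant in the cDC2 gate and nearly absent from EGFP-negative cDC1 lay at a median of 0.021% of their EGFP-positive cDC2 level (2.57% as a share of summed CPM, and 4.74% over a wider gene set), which argues against such cells as the source in that library. Replicate 2 was set against a computed mix of EGFP-negative cDC1 with 15.4% of RNA from the cDC2 gate. For each gene the mix took the higher level of both cDC2 groups. That share was the largest median or share of summed CPM over a gene set, while single genes reached up to 52.6% (Msr1). The list lay above that mix by a median of 0.701 (percentile 99.98), which argues against cells of the gate in their average composition at that share. Larger shares were not tested. Whether a subset of the gate with another profile entered both libraries cannot be told apart from a change in the cells by the replicate 1 median of 1.515, since no library holds such a subset alone. RNA of tumour cells was not tested as a source of these glycolysis values. The epithelial carcinoma list passed no test for EGFP in cDC1, as given above, although its member Cav1 differed widely between the EGFP-positive replicates. Sparc, a matrix gene of the fibroblast and endothelial list, was at 674 CPM in replicate 1, against 0.140 CPM in replicate 2. What stays open is a metabolic difference between EGFP-positive and EGFP-negative cells, tumour RNA, and variation between libraries. This list also differed between the EGFP-negative cDC1 replicates (median 0.223, percentile 97.75).

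Proliferation genes were lower in both EGFP-positive cDC1 libraries, with medians of −3.35 and −3.996 against the EGFP-negative mean. Fewer genes were detected in these libraries, but the list's median lay below those of all 10000 random lists of matched expression (percentile 0). This argues against a loss of weak transcripts that falls on genes at random. Random lists hold unrelated genes, so they cannot speak to proliferation genes being lost together in a library. Camera had called this list too on the same libraries, so the percentile is no separate support. A lower share of dividing cells among EGFP-positive cDC1 may be the biological side. It was not tested further, and the list also differed between the EGFP-positive cDC2 replicates (median 1.858, percentile 100), so library-level variation stays open.

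Replicate 2 of EGFP-positive cDC1 carried myeloid genes that replicate 1 lacked. An admixture of cDC2-gate cells would bring these genes in at 1 common ratio to their EGFP-positive cDC2 level, and genes under 10% of that ratio were counted. With the median ratio of the narrower gene set (1.16%), 50% (1 of 2 genes that would then reach 10 CPM) lay under it, too few to decide. With the ratio of summed CPM of the wider set (15.4%), 33.3% (10 of 30 genes) did, against 6.55% (228 of 3481) of control genes (Fisher's exact test, p = 1.52e-05). Genes of 1 library are not independent replicates, so this p-value measures no spread between samples. The control genes were genes of like level in EGFP-negative cDC1, set against that level. They are genes of cDC1 themselves, so they do not cover uneven loss of genes from a few admixed cells. With the scalings exchanged the shares were 40% (2 of 5) and 27.6% (8 of 29), and the gene-set thresholds were set after marker levels had been seen. Arg1, Apoe, Msr1 and Trem2 stood at 38.2%, 27.2%, 52.6% and 42.4% of their EGFP-positive cDC2 level, against 0.244%, 0.0557%, 0.0543% and 0.0505% for C1qa, Mrc1, Ccl8 and Pf4. These values argue against an admixture that brings the gate's genes in at 1 common ratio. A subset of the gate, or uneven loss of genes from a few of its cells, stays open. The mregDC median of this library against replicate 1 was 2.443 (percentile 100 of the random lists), but members of that list had been seen to differ before and it holds none of these myeloid genes. It therefore decides nothing on mature cells as their source.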

How the results depend on the processing

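Removal of Rn45s was chosen after seeing the data, and the other alternatives were not. Of the results that answer a comparison, 188 kept their direction and side of the threshold (counts within 1.5 times), 32 passed it or rose beyond that and 42 lost it or fell beyond that. Of the values for single genes and lists, each counted once per setting, 6716 stayed on their side of the threshold. A further 546 gained a call, 601 lost one and 3 reversed. A change of sign counted as a reversal only where at least 1 of the 2 fits passed. Itgam for EGFP in cDC1, for example, went from 2.229 to −3.882 by voom with quality weights, passed in neither, and was counted as unchanged. Of 91 calls on named genes, 91 were kept by DESeq2, 90 by RLE scaling, 91 without Rn45s, 87 with the 10 CPM filter, 85 without the low-count filter, 78 by voom and 62 without robust estimation. A fit of the compared libraries only kept 30 of 53, and the 4-group model 37 of 38. In the order EGFP in cDC1, EGFP in cDC2, their difference, subset in EGFP-negative cells, subset in EGFP-positive cells, EGFP over both subsets and subset over both fractions, DESeq2 gave 1325, 110, 714, 838, 1586, 184 and 1160 genes. Without the low-count filter there were 57, 29, 112, 153 and 236 genes for EGFP in cDC1, the difference, subset in EGFP-negative cells, subset in EGFP-positive cells and subset over both. Without robust estimation the 3 subset comparisons gave 25, 12 and 99. By voom with quality weights there were 2 genes for EGFP in cDC2, 1 for the difference, 528 for subset in EGFP-negative cells, 4 for EGFP over both and 872 for subset over both. A fit of the compared libraries only gave 292 genes for subset in EGFP-negative and 0 in EGFP-positive cells (edgeR, 1678 of 10258 at an unadjusted p under 0.05; on all 8 libraries and 11394 genes DESeq2 1586 and voom 22), and the 4-group model gave 275 for subset over both. With an estimated inter-gene correlation, in the same order, 1, 0, 1, 1, 0, 0 and 0 lists passed. For EGFP in cDC1 the medians were then −0.968 for cDC1 identity, 0.702 for mregDC, 1.26 for cholesterol biosynthesis and −6.19 for proliferation, as before, and these calls were lost (adjusted p = 0.696, 0.696, 0.67 and 0.67). The cause of these changes was not tested.

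In the titles, every replicate 1 carries one code and every replicate 2 another, and the labels do not say whether a code stands for an animal, a day or a batch. Correlations between groups of replicate differences ranged from −0.2 to 0.031, and the samples were not treated as pairs. With the replicate number as a block, 3, 0 and 82 genes passed for subset in EGFP-negative cells, EGFP-positive cells and over both (edgeR, 804, 1382 and 1235 at an unadjusted p under 0.05; DESeq2 without the block 838, 1586 and 1160; voom 528, 22 and 872). Of 91 calls on named genes 28 were kept, and of 67 list calls 66.

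Where 1 library was left out, the lone sample of its group was assumed to vary like the other groups. Of the 91 calls on named genes, 35 and 34 were kept without EGFP-negative cDC1 replicates 1 and 2, 89 and 88 without EGFP-positive cDC1, 26 and 21 without EGFP-negative cDC2, and 61 and 56 without EGFP-positive cDC2. Gene counts ranged from 0 to 1050 for EGFP in cDC1, where the 2 EGFP-positive cDC1 libraries gave 763 (without replicate 1) and 1050 (without replicate 2). They ranged from 0 to 668 for the difference, from 1 to 465 for subset in EGFP-negative cells, from 1 to 1273 for subset in EGFP-positive cells and from 50 to 277 for subset over both, the highest without an EGFP-positive cDC1 library. List counts ranged from 4 to 13 for EGFP in cDC1, 3 to 11 for EGFP in cDC2, 2 to 11 for the difference and 6 to 13 for EGFP over both. Among medians for EGFP in cDC1, cDC1 identity ranged from −1.07 to −0.67, mregDC from −0.34 (without EGFP-positive replicate 2) to 2.04 (without EGFP-positive replicate 1), cholesterol biosynthesis from 0.13 (without EGFP-positive replicate 1) to 2.34, glycolysis from 1.47 to 2.04 and proliferation from −7.87 to −5.86. The last 2 kept their calls without any 1 library. Itgam reversed without EGFP-positive cDC1 replicate 2, to −8.59 for EGFP in cDC1 (adjusted p = 0.00157) and −8.22 for the difference (adjusted p = 0.00397), and was 3.23 and 3.61 without EGFP-positive cDC1 replicate 1. In the group, replicate 1 had 0.0438 CPM of Itgam and replicate 2 had 181 CPM. The lysosome list for subset in EGFP-positive cells ranged from −1.35 to −0.48, and without EGFP-positive cDC2 replicate 1 its median was −0.68 with the test turning upward (adjusted p = 0.989).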

Other observations

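The genes Irf7, Rab43, Tnfaip2, Cxcl9 and Egr2 in this part were named after their values were seen, and the splits of the libraries were planned. Interferon response genes passed no list test in any of the 7 comparisons. Within that list Irf7, a transcription factor of the type I interferon response, was higher in cDC1 than in cDC2 over both EGFP fractions (1.96 ± 0.39, adjusted p = 0.0449), while the list had a median of −0.67 and an upward test (adjusted p = 0.454). The cross-presentation list passed no test either (median −0.27, test upward, adjusted p = 0.379 over both fractions), with Wdfy4 and the vesicle traffic gene Rab43 (1.69 ± 0.34, adjusted p = 0.0488) higher in cDC1. Herpud1 was the unfolded protein response gene past the threshold over both fractions (2.69 ± 0.49, adjusted p = 0.0337; list median 0.19, adjusted p = 0.0517). On the lower side in cDC1 were Cxcl9, a chemokine gene that attracts T cells (−1.82 ± 0.34, adjusted p = 0.0359), Tnfaip2 (−1.99 ± 0.36, adjusted p = 0.0331) and the immediate early gene Egr2 (−1.95 ± 0.35, adjusted p = 0.0337). Their lists, T-cell attracting chemokines, NF-kB and inflammatory genes, and stress genes, did not pass (adjusted p = 0.454, 0.0577 and 0.476).

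Of the peptidases related to Dpp4, Dpp3 was at 28.7 ± 4.81, 40.7 ± 23.7, 39.6 ± 2.44 and 31.4 ± 0.219 CPM in EGFP-negative cDC1, EGFP-positive cDC1, EGFP-negative cDC2 and EGFP-positive cDC2, and Prcp at 167 ± 72.3, 94.97 ± 37.7, 100.4 ± 5.26 and 56.6 ± 24.4 CPM (n = 2 libraries per group). Plet1, a surface protein gene placed in the epithelial carcinoma list, was at 1411 ± 794 and 1558 ± 642 CPM in the cDC1 groups and 1.07 ± 0.0629 and 11.5 ± 15.9 CPM in the cDC2 groups. Neutrophil genes were low, with S100a8 at 0 and 0.0219 ± 0.0309 CPM in the cDC1 groups and 10.3 ± 2.66 and 10.2 ± 10.8 CPM in the cDC2 groups, and the list of 4 tested members passed no comparison (adjusted p = 0.051 for subset over both fractions). B-cell (3 tested members) and plasmacytoid dendritic cell (8) lists passed none either (adjusted p = 0.711 and 0.472 for subset over both fractions).

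The grouping itself was set against other splits of the 8 libraries into 4 and 4. For subset over both fractions, 1 of 34 splits, the real one, gave as many genes (150, against 1 in the highest other). The real split stood apart, but 1 of 34 is the smallest share that this test can give, so chance is not excluded. The other splits also left the difference between the subsets in the spread, which lowers their counts. For the count of lists, 4 of 34 splits gave as many (12, against 13), so chance cannot be excluded there either. For EGFP over both subsets the real count of genes was 0, so that all 34 of 34 splits necessarily gave as many (highest other 2) and this test says nothing on genes (edgeR, 595 at an unadjusted p under 0.05, DESeq2 184, voom 4). For lists chance cannot be excluded (15 of 34, real count 8, highest other 14).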
